A study of Rattus norvegicus with 6 samples.

How the data were processed

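Total RNA from the hippocampus of 3 saline-treated and 3 nicotine-treated rats received small RNA adapters at both ends, and after reverse transcription, PCR and size selection on a gel the libraries were read on an Illumina NextSeq, per the labels' protocols. The submitters' processing notes name FastQC, cutadapt and Bowtie without versions. The genome build and the tRNA annotation are not given in the sources used here. The deposited values are CPM for 615 named fragments per library, and 2 of the 6 files carry no unit in their header and were read as CPM from their values. Each CPM value was a whole multiple of the value of 1 read within a tolerance of 0.001 reads, for 100% of the values in every library. Whole reads and the library total that the authors divided by were recovered from this step. Which reads that total includes is not stated, and the listed fragments made up 47.1% to 68.8% of it. Every fragment had at least 20 CPM in at least 1 library (lowest maximum 21.3 CPM), so the list depends on depth. Fragments were named as in the files, and coordinates in the genome were not used here.

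The class of each fragment was assigned here from the position and length in its name, since the files name no class. tRF-5a, tRF-5b and tRF-5c start at the first base and had 14 to 16, 22 to 24 and 28 to 32 nt, and tiRNA-5, named tiRNA in the files, had 20 to 35 nt. tRF-3a and tRF-3b end in the CCA tail and had 17 to 18 and 19 to 22 nt, tiRNA-3 had 36 to 40 nt, tRF-2 were internal with 14 to 15 nt, and tRF-1 were trailers with 14 to 33 nt. Groups and replicate numbers were taken from the sample titles, which number the rats. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 11.9 to 24.4, so no library was counted as a duplicate.

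Because the files hold CPM, the main test was limma 3.58.1 (trend and robust) in R 4.3.3 on log2(CPM + 1), for fragments with at least 1 CPM in at least 3 libraries, two-sided, with Benjamini-Hochberg adjustment at 0.05. The pseudocount of 1 CPM lies below the value of 1 read, 2.67 to 11.0 CPM, so fitted fold changes of fragments with 0 reads in some libraries depend on it and are no bound. Of 615 fragments 586 were tested, and of 178 families, summed over class and anticodon, 172. Recovered reads were also tested with edgeR 4.0.16 (quasi-likelihood), limma-voom and DESeq2 1.42.0 as alternatives added after the data were seen. Shares, length and numbers of detected fragments were compared with exact two-sided permutation tests in scipy 1.17.1, whose smallest p is 0.1 for 3 against 3 libraries. Share intervals are 95% Wilson intervals, and the floor of a fragment at 0 reads is 3 reads over the group. Lists of fragments were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Of 15 lists fixed before the data were examined, 14 were tested. The list of 5' fragments that begin with a run of G was not tested, because it needs sequences that were not used here.

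Named fragments were chosen by a rule fixed before the data were examined. It took the 10 largest changes per direction among fragments past the threshold without overlap, filled up by the smallest unadjusted p, and the 10 with the highest mean CPM, and for families 5 by p and 5 by mean. As none passed, all 20 came from the unadjusted p. The amino acids described were chosen after their values were seen, as the 5 most abundant and those without overlap in shares or CPM, with tryptophan, histidine and serine singled out besides.

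The tests were checked on simulated data with known changes. In 20 simulations of the fragment comparison (median of 579 tested fragments), 72.8% of fragments changed 8-fold and 9.8% of those changed 2-fold were recovered, and at a mean of at least 100 CPM 97.7% and 23.8%. For families changed 8-fold (median of 171 tested) 81.4% were recovered, and a 2-fold rise of the tRF-3 list among 14 lists was recovered in 20 of 20. With no change simulated, 0 of 20 had a fragment or list call, and the median log2 fold change lay between -0.16 and -0.03. Fragments were simulated independently of each other, so neither the family check nor either list check covers correlated members. In the data the estimated correlation was 0.18 for tRF-3 and 0.46 for the 5' fragments of His tRNAs. Where changes were simulated, a simulation called at most 4 unchanged fragments or families. Alternatives covered the scaling, pseudocounts of 0.5 and 10, filters, the threshold, the test, a replicate block, thinning to the smallest total and leaving out each library in turn.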

Results

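Small RNAs derived from transfer RNAs (tRNAs) were sequenced from the hippocampus, a brain region of memory and reward learning, of Sprague-Dawley rats aged 6 to 8 weeks. The rats had received nicotine, the addictive alkaloid of tobacco, or saline, with 3 libraries from separately numbered rats in each group. The values were CPM, read counts scaled to the total of each library, for 615 fragments, of which 480 came from nuclear and 135 from mitochondrial tRNAs. The read totals implied by the CPM values were 374763, 154414 and 206221 in the saline libraries and 90828, 122282 and 128694 in the nicotine libraries. All 3 nicotine libraries were therefore shallower than every saline library, and depth and treatment cannot be separated in this design. Listed fragments took 60.8% ± 8.03 of the total in saline and 51.2% ± 5.44 in nicotine libraries (SD, n = 3 each, exact two-sided permutation p = 0.2). A listed fragment had at least 20 CPM in at least 1 library, a level that 2 reads met in nicotine 1 and that took 8 reads in saline 1. Of the 615 fragments, 151 reached 20 CPM in 1 library alone, and for 87 of them that library was nicotine 1. Intervals from read numbers cover counting error only, since the protocols describe no molecular identifiers.

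The first comparison asked whether the kinds of tRNA fragment differed after nicotine. In both groups most listed reads were 5' fragments of 28 to 32 nt (tRF-5c), the products of a cut in or near the anticodon loop. They took 84.1% ± 3.24 of the listed reads in saline and 77.4% ± 3.11 in nicotine libraries (SD, n = 3 each). The short 3' fragments that end in the CCA tail of the mature tRNA took larger shares in the 3 nicotine libraries than in any saline library. Those of 17 to 18 nt (tRF-3a) took 2.67% ± 0.548 in saline and 4.57% ± 1.87 in nicotine, and those of 19 to 22 nt (tRF-3b) took 0.552% ± 0.125 and 0.976% ± 0.213 (SD, n = 3 each). Shorter 5' fragments had the same direction, with 1.39% ± 0.384 and 2.25% ± 0.436 for tRF-5b and 0.922% ± 0.236 and 1.36% ± 0.188 for tRF-5a (SD, n = 3 each). Internal fragments (tRF-2) took 0.0670% ± 0.0216 and 0.119% ± 0.0255 (SD, n = 3 each). For these 6 classes the 3 nicotine libraries lay on one side of the 3 saline libraries, 5 of them higher and tRF-5c lower, where chance gives 10% of classes. The exact two-sided permutation p was 0.1 for each, the smallest that 3 against 3 libraries allow, with a Benjamini-Hochberg adjusted p of 0.15 over 9 classes, so none passed the threshold. The shares of a library sum to a fixed whole, so a lower tRF-5c share raises the others together. The classes are therefore not independent chances. Relative to the library total (CPM), tRF-5b, tRF-5a, tRF-3b and tRF-2 were higher without overlap (adjusted p = 0.225), and tRF-5c and tRF-3a overlapped (exact permutation p = 0.2 each).

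The groups overlapped for the other 3 classes. The 5' tRNA-derived stress-induced RNAs (tiRNA-5), long fragments made when stress nucleases cut the anticodon loop, took 6.03% ± 1.68 of the listed reads in saline and 7.06% ± 1.05 in nicotine libraries (SD, n = 3 each, exact permutation p = 0.4). The trailer fragments cut from the 3' end of the precursor tRNA (tRF-1) took 4.22% ± 1.27 and 6.21% ± 1.90 (SD, n = 3 each, exact permutation p = 0.3). The long 3' fragments of the mature tRNA (tiRNA-3) took 0.0587% ± 0.0210 and 0.0896% ± 0.0270 (SD, n = 3 each, exact permutation p = 0.3). Mitochondrial tRNA fragments took 1.97% ± 0.534 in saline and 3.46% ± 1.16 in nicotine libraries without overlap (SD, n = 3 each, exact permutation p = 0.1), and overlapped on CPM (exact permutation p = 0.2). The closest shares nearly tied, at 2.32% in saline 2 (95% Wilson interval 2.23 to 2.42) and 2.34% in nicotine 2 (2.23 to 2.45). Nicotine 1 lay farthest from the other libraries in several of these shares. Its tRF-3a share was 6.72% (95% Wilson interval 6.49 to 6.95), against 3.40% and 3.58% in the other nicotine libraries. Without nicotine 1 the difference between groups went from 1.90 to 0.823 percentage points for tRF-3a and from 1.49 to 0.902 for mitochondrial fragments, still without overlap. With Gly tRNA fragments left out of all 6 libraries the groups overlapped for mitochondrial fragments (9.47% and 12.96%, exact permutation p = 0.2), tRF-5c (32.5% and 23.8%, p = 0.2), tRF-3a (p = 0.3) and tRF-2 (p = 0.2). tRF-3b, tRF-5a and tRF-5b stayed higher in nicotine without overlap.

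**Figure D1:**
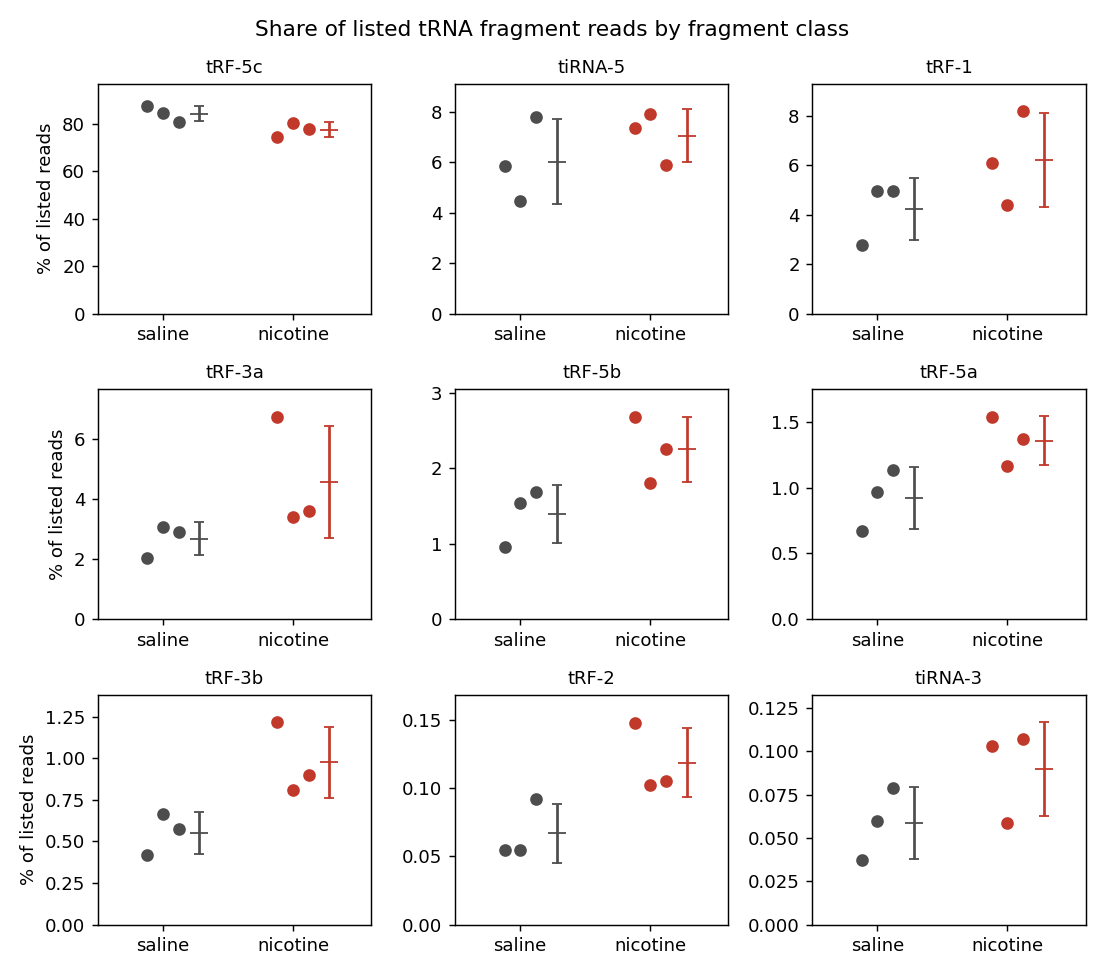
Share of listed tRNA fragment reads (%, vertical axes from 0) by fragment class in 3 saline and 3 nicotine libraries, with 1 point per library and bars for the mean ± SD. The tRF-5c share was 84.1% in saline and 77.4% in nicotine libraries, and nicotine 1 stood apart for tRF-3a at 6.72%.

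The second comparison concerned the parent tRNAs. Fragments of glycine tRNAs took 79.3% ± 4.45 of the listed reads in saline and 73.6% ± 3.91 in nicotine libraries (SD, n = 3 each, exact permutation p = 0.2). Valine tRNA fragments took 3.13% ± 0.137 and 4.16% ± 0.129, and the 3 nicotine libraries all lay above the 3 saline libraries (SD, n = 3 each, exact permutation p = 0.1). The same held for alanine (1.16% ± 0.280 and 1.70% ± 0.337), glutamine (0.807% ± 0.203 and 1.35% ± 0.229), leucine (0.692% ± 0.154 and 1.12% ± 0.277) and cysteine (0.226% ± 0.0717 and 0.373% ± 0.0626, SD, n = 3 each). These 5 of 20 amino acids were singled out after their values were seen, chance gives 10%, and their Benjamini-Hochberg adjusted p was 0.333 by the exact permutation test. The amino acid shares are not independent either, since a lower glycine share raises the others together. On CPM the groups overlapped for valine (19032 CPM in saline and 21312 CPM in nicotine, exact permutation p = 0.6), alanine and cysteine, and glutamine, leucine and tyrosine were higher without overlap. The groups overlapped for the other abundant parents. Glutamate tRNA fragments took 3.64% ± 0.772 and 3.20% ± 1.42, lysine 3.52% ± 1.54 and 3.93% ± 0.495, and methionine 2.22% ± 0.641 and 3.02% ± 0.661 (SD, n = 3 each). The glutamate difference of -0.434 percentage points turned to 0.0548 without nicotine 1, and the lysine difference of 0.412 turned to -0.237 without saline 2. Without nicotine 1 the difference went from 0.543 to 0.349 percentage points for alanine and from 0.427 to 0.269 for leucine. That of glycine went from -5.74 to -3.32 without saline 1, and that of methionine from 0.796 to 0.456 without nicotine 3.

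Single fragments were then compared between the groups. The most abundant was the 32 nt 5' fragment of tRNA Gly-CCC, tRF-1:32-Gly-CCC-1-M2, at 254662 CPM ± 50415 in saline and 180278 CPM ± 38367 in nicotine libraries (SD, n = 3 each). Its log2 fold change was -0.50 (SE 0.35), and all 3 nicotine values lay below all 3 saline values. Its 31 nt and 30 nt forms, tRF-1:31-Gly-CCC-1-M2 and tRF-1:30-Gly-CCC-1-M2, had log2 fold changes of -0.22 and -0.15, within the spread of the libraries. The Gly-GCC fragments tRF-1:32-Gly-GCC-2-M2 and tRF-1:31-Gly-GCC-2-M2 had log2 fold changes of -0.66 (SE 0.37) and -0.26 (SE 0.37). The 5' ends of Gly-CCC and Gly-GCC tRNAs are nearly identical, so how reads were divided between these names is uncertain. The tiRNA-5 fragments tiRNA-1:34-Lys-CTT-1 and tiRNA-1:33-Gly-GCC-1 had 12908 CPM ± 4737 against 12765 CPM ± 3573 and 7895 CPM ± 1859 against 8527 CPM ± 3344 (saline against nicotine, SD, n = 3 each). The 5' fragment tRF-1:32-Val-AAC-1-M3 had a log2 fold change of -0.21. The trailer fragments tRF-+1:T15-iMet-CAT-1 and tRF-+1:T16-iMet-CAT-1, from the initiator methionine tRNA, had 0.18 and 0.16.

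None of the 586 tested fragments passed a Benjamini-Hochberg adjusted p of 0.05 in limma, where the smallest was 0.657. At an unadjusted p under 0.05 there were 41 fragments, 30 higher and 11 lower in nicotine, where chance gives 29.3. With a library left out there were 24 without saline 1 (chance 28.5) to 53 without nicotine 3 (chance 29). Without nicotine 1 there were 27 (chance 28.6). Other divisions of the 6 libraries into 3 and 3 gave up to 48. On the recovered reads edgeR with TMM passed 0 of 221 fragments, with 15 at an unadjusted p under 0.05 (2 higher, 13 lower, chance 11.1). DESeq2 passed 0 of 615, with 17 (2 higher, 15 lower), below the 30.8 that chance gives. With no scaling factor edgeR passed 0, with 22 (18 higher, 4 lower, chance 11.1). The groups did not overlap for 83 fragments (14.2%, against 10% by chance), 74 higher and 9 lower. The balance of directions moved with the scaling. The median log2 fold change was 0.28 on the deposited CPM and -0.08 after TMM rescaling, where the 33 fragments at an unadjusted p under 0.05 divided into 6 higher and 27 lower.

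Among the 10 fragments higher in nicotine with the smallest p, 5 were tRF-1 trailer fragments, which made up 112 of the 586 tested. The mitochondrial trailer tRF-+1:T26-chrM.Trp-TCA-M1-25:C>T had 39.3 CPM ± 21.5 in saline and 148 CPM ± 85.0 in nicotine libraries, a log2 fold change of 1.91 (SE 0.58, SD, n = 3 each). The trailer tRF-+1:T28-His-GTG-1 had 53.2 CPM ± 43.2 and 142 CPM ± 39.5, and tRF-+1:T15-Asp-GTC-2-10-M3 had 97.4 CPM ± 57.2 and 217 CPM ± 41.3 (SD, n = 3 each). tRF-+1:T16-Cys-GCA-5-20 and tRF-+1:T28-Gln-CTG-5-2 had log2 fold changes of 2.28 (SE 0.79) and 1.86 (SE 0.79), or 1.29 to 3.26 and 1.34 to 2.59 with a library left out. The 3' fragments tRF-61:77-Ile-AAT-1-M3 and tRF-60:76-Lys-CTT-1-M3 had 80.9 CPM ± 92.1 and 66.4 CPM ± 66.6 in nicotine libraries, a spread set by nicotine 1 at 187 CPM and 143 CPM. The 3' fragment tRF-57:75-Ala-AGC-3 had 76.8 CPM ± 58.8 and 170 CPM ± 54.1 (SD, n = 3 each). The 5' fragments tRF-1:31-chrM.Ser-GCT and tRF-1:15-Leu-CAA-1-M5 had 321 CPM ± 125 against 590 CPM ± 80.7 and 98.6 CPM ± 15.3 against 209 CPM ± 39.0 (SD, n = 3 each).

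Of the 10 fragments lower in nicotine with the smallest p, 8 were 5' fragments. Among the 586 tested fragments 256 were tRF-5 and 40 were tiRNA-5. The 5' fragment of Glu-CTC, tRF-1:31-Glu-CTC-1, was the most abundant of them, at 5744 CPM ± 1906 in saline and 3145 CPM ± 2884 in nicotine libraries (SD, n = 3 each), and nicotine 3 at 6434 CPM lay within the saline range. tRF-1:30-Glu-TTC-4 had 342 CPM ± 130 and 178 CPM ± 62.4, and tRF-1:15-Lys-TTT-1 had 76.9 CPM ± 9.04 and 31.3 CPM ± 9.44 without overlap (SD, n = 3 each). Of 3 fragments of Pro-AGG, tRF-1:31-Pro-AGG-1-M4 had 134 CPM ± 58.6 and 54.2 CPM ± 60.8, and tRF-1:29-Pro-AGG-1-M5 had 39.6 CPM ± 25.4 and 13.4 CPM ± 12.4 (SD, n = 3 each). The third, tRF-1:28-Pro-AGG-1-M5, had 14 reads in the saline libraries and 0 in the nicotine libraries. Its pooled saline CPM was 2.17 times a floor of 3 reads over the nicotine group. That ratio leaves out the error of the 14 reads and the spread between libraries, so it is no bound. The other 4 were read rarely in nicotine, and the groups overlapped for each. tRF-1:15-Thr-TGT-4 and tRF-1:29-Val-AAC-2 had 12.95 CPM ± 22.4 and 10.9 CPM ± 18.9 there, against 34.4 CPM ± 16.3 and 30.3 CPM ± 13.6 in saline libraries (SD, n = 3 each). Nicotine 3 at 38.9 CPM of the former and nicotine 2 at 32.7 CPM of the latter lay inside the saline range. The remaining nicotine libraries had 0 reads of these fragments. The trailers tRF-+1:T14-iMet-CAT-1-M1-12:T>C and tRF-+1:T14-Met-CAT-2-2 had 3.67 CPM ± 6.36 and 8.85 CPM ± 7.99, against 21.9 CPM ± 9.84 and 39.3 CPM ± 27.3 (SD, n = 3 each).

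**Figure D2:**
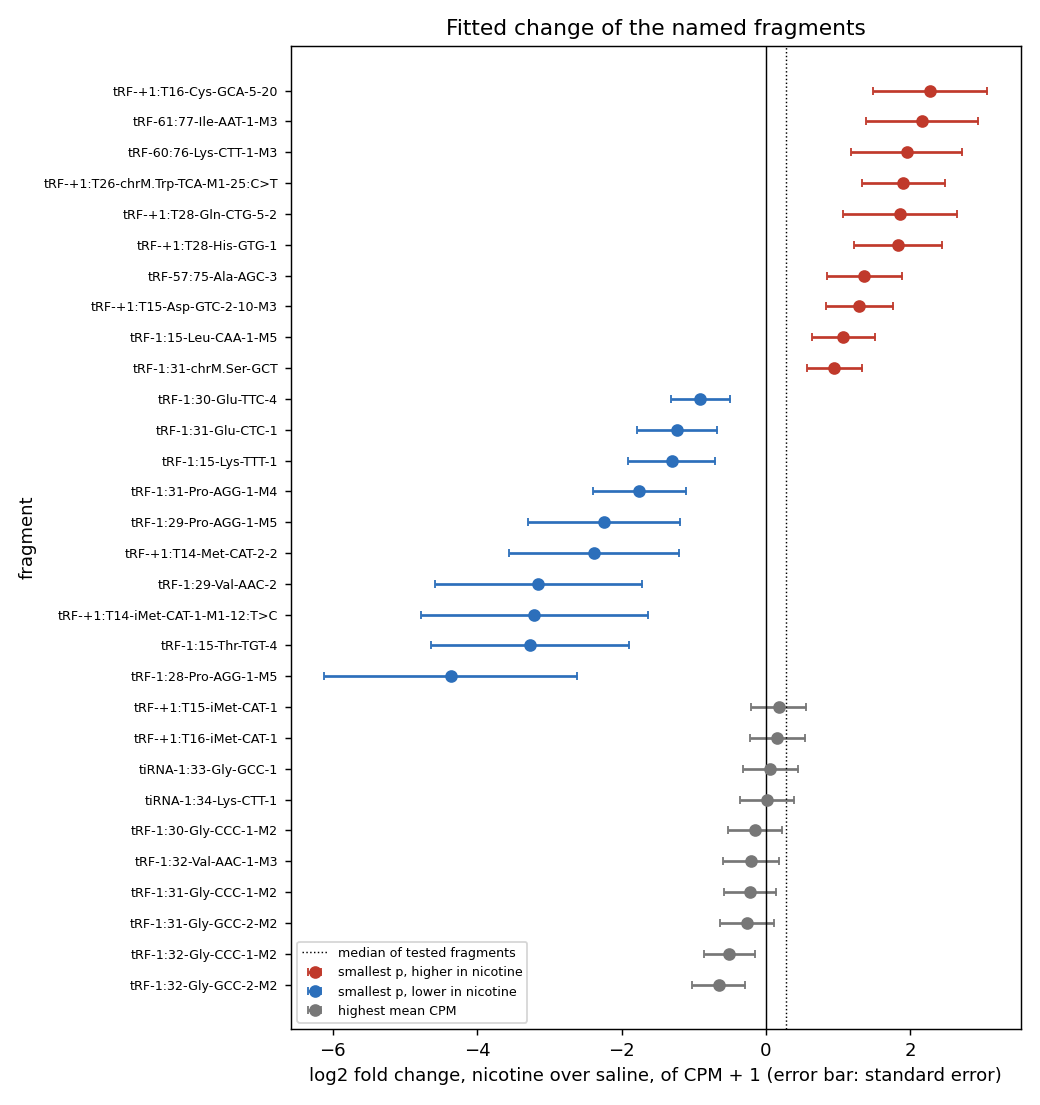
Log2 fold change of CPM + 1, nicotine over saline (horizontal axis), for 30 named fragments, with points for the fitted change from 3 libraries per group and bars for the standard error. The abundant fragments lay between -0.66 and 0.18, and the dotted line marks the median of all tested fragments at 0.28.

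Fragments were also summed over each class and anticodon. The family of tRF-5 from Gly-CCC had 436721 CPM ± 87287 in saline and 337937 CPM ± 61125 in nicotine libraries, with overlap, and tRF-5 from Gly-GCC had 36177 CPM ± 2887 and 27479 CPM ± 3166, without overlap (SD, n = 3 each). The families of tiRNA-5 of Lys-CTT, tRF-5 of Val-AAC and tRF-1 of iMet-CAT had log2 fold changes of 0.02, 0.15 and 0.17, all of which turned negative after TMM rescaling. The smallest p belonged to tRF-3 of Ser-GCT, with 90.2 CPM ± 31.6 and 221 CPM ± 72.0 (SD, n = 3 each). It was followed by tRF-1 of mitochondrial Trp-TCA, tRF-1 of Cys-GCA, tRF-5 of mitochondrial Met-CAT and tRF-3 of Tyr-GTA, with log2 fold changes of 1.34, 1.61, 0.76 and 0.74. Leaving out saline 1 took tRF-1 of Cys-GCA to 0.87, and leaving out nicotine 1 took tRF-3 of Tyr-GTA to 0.48. None of the 172 tested families passed in limma (smallest adjusted p = 0.542). At an unadjusted p under 0.05 there were 14 families, all higher in nicotine, where chance gives 8.6, and after TMM rescaling there were 10, of which 3 were higher and 7 lower. With a library left out there were 7 without nicotine 1 (6 higher, 1 lower, chance 8.3) to 20 without nicotine 3 (14 higher, 6 lower, chance 8.5). Other divisions of the 6 libraries into 3 and 3 gave up to 17. On recovered reads edgeR with TMM and DESeq2 passed 0 families, with 7 (chance 5.2) and 6 (chance 8.9) at an unadjusted p under 0.05, all lower. edgeR passed 0 with upper quartile scaling, with 8 (2 higher, 6 lower, chance 5.2), and 0 with no scaling factor, with 14, all higher (chance 5.2). limma-voom passed 0, with 12 (3 higher, 9 lower, chance 5.2).

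Lists of fragments fixed before the data were examined were tested as groups against the other fragments with camera. Of all 586 tested fragments 378 were higher in nicotine on the deposited CPM, and 259 after TMM rescaling. The numbers of members higher or lower are to be read beside that share, and they depend on the scaling. The CCA-ended tRF-3 list lay above the other fragments, with 132 of 159 members higher in nicotine and a mean log2 fold change of 0.52 (adjusted p = 0.00128, and 0.504 with an estimated correlation). Fragments of Leu, Ser and Tyr tRNAs, listed for the long variable arm or intron of their nuclear forms, also lay above, with 85 of 110 higher and a mean of 0.43 (adjusted p = 0.0303, and 0.504 with an estimated correlation). Of the 110, 26 were mitochondrial, and without them the list did not pass, with 63 of 84 higher and a mean of 0.43 (adjusted p = 0.0575). The 5' fragments of Glu tRNAs lay below the others, with 30 of 36 lower and a mean of -0.30 (adjusted p = 3.87e-07, and 0.125 with an estimated correlation). The 5' fragments of Gly tRNAs had 25 of 38 lower and a mean of -0.09 (adjusted p = 0.00124, and 0.125 with an estimated correlation). The 5' fragments of His tRNAs had 6 of 10 lower and a mean of -0.25 (adjusted p = 0.0303, and 0.504 with an estimated correlation). The tiRNA-5 had 23 of 40 lower, and the tiRNA-5 known from blood plasma, a stand-in for blood left in the tissue, had 13 of 22 lower (adjusted p = 0.0303 and 0.0347, and 0.504 for both with an estimated correlation). The tRF-5 list lay below the other fragments although 139 of its 256 members were higher and its mean was 0.05 (adjusted p = 0.00124, and 0.125 with an estimated correlation).

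In all, 8 of the 14 lists passed with camera's preset correlation and 0 with an estimated correlation. Without nicotine 1 there were 3, namely tRF-1 and the 5' fragments of Gly and Glu tRNAs, with adjusted p of 0.715, 0.698 and 0.715 at an estimated correlation. The mean of the tRF-3 list went from 0.52 to 0.21 without nicotine 1, its difference from the other fragments from 0.37 to 0.059, and its adjusted p to 0.506. For the 5' fragments of Glu tRNAs the mean went from -0.30 to -0.18 without nicotine 1, and the difference from -0.59 to -0.37. Without saline 1 there were 5 lists past the threshold. With reads thinned to the smallest library total the median over 20 draws was 7 lists, and the median adjusted p went to 0.0524 for the tiRNA-5 and 0.0565 for the 5' fragments of His tRNAs. With all libraries tRF-1 trailers (76 of 112 higher, adjusted p = 0.0575) and mitochondrial fragments (91 of 121 higher, adjusted p = 0.0573) did not pass, nor did tRF-2 (0.564), tiRNA-3 (0.900) or the 5' fragments of Lys (0.0842) and Val tRNAs (0.805). The trailers and mitochondrial fragments passed camera at the preset correlation with the replicate number as a block (adjusted p = 0.0478 for both). They also passed over fragments with at least 20 CPM in every library (adjusted p = 0.0279 and 0.000694). Neither passed with an estimated correlation (adjusted p = 0.635 for both). For the tiRNA-3 the mean and median were above 0 and camera's direction was down. The 5' fragments of Val tRNAs also had a mean above 0 with camera's direction down. No member of any list passed over all fragments tested, and 0 passed when adjusted over the list alone.

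**Figure D3:**
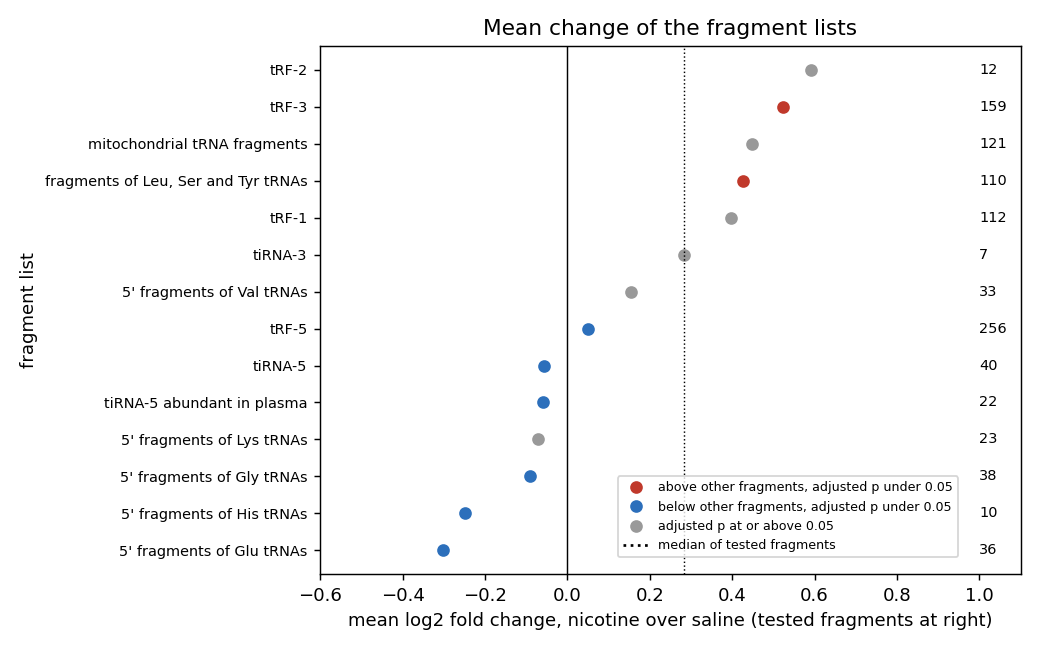
Mean log2 fold change, nicotine over saline (horizontal axis), of 14 fragment lists, with the number of tested members at the right and the median of all tested fragments as a dotted line. The tRF-3 list lay at 0.52 and the 5' fragments of Glu tRNAs at -0.30, and 0 of the 8 coloured lists passed with an estimated correlation.

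The mean fragment length weighted by abundance was 30.3 nt ± 0.374 in saline and 29.5 nt ± 0.450 in nicotine libraries (SD, n = 3 each, exact permutation p = 0.2). The libraries held 557 ± 17.2 and 544 ± 17.2 fragments above 0 (SD, n = 3 each, exact permutation p = 0.4). This order turned when each library was thinned to the smallest read total, with 488 ± 17.9 and 527 ± 30.96 fragments (SD, n = 3 each, exact permutation p = 0.1). The difference of 39.7 was 21.95 without nicotine 1, and 20.3 over the 528 fragments that reached 20 CPM in another library, without overlap (exact permutation p = 0.1). This choice does not remove the listing minimum from the comparison. In the full list 16 fragments reached 20 CPM in nicotine 2 alone and 27 in nicotine 3 alone. For saline 1, 2 and 3 these numbers were 2, 11 and 8. Present in all 3 libraries of one group and at 0 reads in the other were tRF-1:28-Pro-AGG-1-M5 and tRF-1:32-Val-TAC-1 in saline, with 14 and 8 reads, and tRF-1:24-chrM.Val-TAC in nicotine, with 5 reads. The mean rank correlation of a library with the others was 0.767 for nicotine 1 and 0.828 to 0.860 for the other 5, and the first principal component, with 34.1% of the variance, set nicotine 1 apart.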

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

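Chosen after the data were seen were the count tests on recovered reads, the mean CPM filter, thinning for fragments, families and lists, the added list settings, the Leu, Ser and Tyr list without mitochondrial members, and the shares without Gly tRNA fragments or over fragments with at least 20 CPM in every library. In simulation 9.8% of fragments changed 2-fold were recovered, and 23.8% at a mean of at least 100 CPM. The cause was not tested for any value below unless it is named. The count of 0 fragments past the threshold became 1 with limma without trend and robust (tRF-1:28-Pro-AGG-1-M5, lower, adjusted p = 0.0241) and 0 to 5 with a library left out. The 1 without saline 2 was tRF-+1:T16-Cys-GCA-5-20. The 5 without nicotine 3, all lower, were tRF-1:31-His-GTG-1, tRF-1:31-Pro-AGG-1-M4, tRF-1:31-Glu-TTC-4, tRF-1:31-Glu-CTC-1 and tRF-1:16-Ser-AGA-1-M6. The families went from 0 to between 0 and 2, with tRF-5 His-GTG and tRF-5 Pro-AGG lower without nicotine 3. These names were chosen after their values were seen. At an unadjusted p under 0.05 with at least a 1.5-fold change there were 41 fragments and 14 families. Same-numbered libraries had correlations of their deviations from the group means of 0.087, 0.109 and 0.161, and each library correlated best with its own number, a hint from the data and not from the design. With the replicate number as a block there was 1 fragment (tRF-1:31-His-GTG-1, lower, adjusted p = 0.00698), 0 families and 10 lists.

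The 8 lists past the threshold became 0 with an estimated correlation, 0 with fry's test of direction, and 3 to 10 with a library left out, the 3 without nicotine 1. fry's test of changes in either direction gave an unadjusted p of 4.62e-05 for 5' fragments of Val tRNAs and 0.00327 for tRF-5. It gave 0.0879 or more for the other lists. With an estimated correlation and without nicotine 1, a setting of both choices, there were 0. fry, which tests the direction of a list by itself, gave the direction up where camera gave down for 4 lists. These were tiRNA-3, tRF-5 and the 5' fragments of Val and of Lys tRNAs. Their mean log2 fold changes in limma were 0.28, 0.050, 0.15 and -0.071. With an estimated correlation without nicotine 1 the 5' fragments of Val tRNAs lay at -0.0195 with camera's direction turned. With a pseudocount of 10 the tiRNA-3 lay 0.088 from the other fragments with the direction turned. With a library left out the difference from the other fragments ran from -0.34 to 0.26 for tiRNA-3, from -0.53 to 0.10 for 5' fragments of Val tRNAs from -0.070 to 0.36 for tRF-1, from -0.026 to 0.39 for mitochondrial fragments and from 0.059 to 0.66 for tRF-3. The lowest of the mitochondrial and tRF-3 lists were without nicotine 1, against 0.25 and 0.37 with all libraries. Without its mitochondrial members the Leu, Ser and Tyr list lay 0.21 above the others and did not pass.

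Abundant fragments and families near 0 turned with the scaling, which by its construction shifts all fragments of a library alike. In the order TMM, median ratio, edgeR with TMM, edgeR with upper quartile, limma-voom and DESeq2, the log2 fold changes were -0.37, -0.32, -0.34, -0.24, -0.28 and -0.37 for tiRNA-1:34-Lys-CTT-1 and -0.32, -0.27, -0.19, -0.10, -0.23 and -0.23 for tiRNA-1:33-Gly-GCC-1. They were -0.21, -0.16, -0.13, -0.074, -0.13 and -0.17 for tRF-+1:T15-iMet-CAT-1 and -0.23, -0.18, -0.14, -0.093, -0.14 and -0.18 for tRF-+1:T16-iMet-CAT-1. Families in the same order had -0.39, -0.37, -0.54, -0.45, -0.44 and -0.45 (tiRNA-5 Lys-CTT), -0.26, -0.25, -0.31, -0.22, -0.32 and -0.23 (tRF-5 Val-AAC) and -0.24, -0.23, -0.31, -0.23, -0.31 and -0.24 (tRF-1 iMet-CAT). In edgeR with no scaling factor tiRNA-1:34-Lys-CTT-1 had -0.016 and the tiRNA-5 Lys-CTT family -0.047. tRF-1:31-Gly-GCC-2-M2 had 0.036 after quantile normalization. With a library left out the ranges were -0.30 to 0.26 for tiRNA-1:34-Lys-CTT-1, -0.23 to 0.33 for tiRNA-1:33-Gly-GCC-1, -0.024 to 0.39 for tRF-+1:T16-iMet-CAT-1, -0.41 to 0.10 for tRF-1:30-Gly-CCC-1-M2, -0.52 to 0.090 for tRF-1:32-Val-AAC-1-M3 and -0.33 to 0.33 for the tiRNA-5 Lys-CTT family. They were -0.62 to -0.32 for tRF-1:32-Gly-CCC-1-M2, -0.46 to -0.025 for tRF-1:31-Gly-CCC-1-M2 and -0.45 to -0.10 for tRF-1:31-Gly-GCC-2-M2. The 10 named fragments higher and the 10 lower by p kept their direction with each library left out, and 6 of each moved by over 1.5 times.

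Differences in the shares of the 9 classes, tRF-3, tRF-5, mitochondrial fragments and the 20 amino acids kept their direction with each library left out (-8.38 to -5.11 points for tRF-5c, 1.13 to 2.99 for tRF-3), except Glu (-1.25 to 0.0548), Lys (-0.237 to 1.26) and Pro (-0.00565 to 0.0535, negative without nicotine 3). The tiRNA-5 difference of 1.03 points ran from 0.243 without saline 2 to 1.92 without saline 3. That of tRF-1, 1.99 points, ran from 1.01 without nicotine 3 to 2.90 without nicotine 2. With each detected fragment counted once the difference in percent of fragments turned to -0.0950 for tiRNA-3, -0.00658 for tiRNA-5, -0.0749 for tRF-1, -0.0154 for tRF-2, 0.111 for Gly, -0.00546 for Lys, -0.238 for Val, -0.161 for Met, -0.171 for Ala, -0.0214 for Gln, -0.174 for Cys, -0.0540 for Asp, 0.351 for His, -0.0240 for Phe, -0.0549 for Pro and -0.341 for Thr. Without Gly tRNA fragments the tiRNA-5 difference was -2.02 points, and without the most abundant fragment that of Lys was -7.49e-05. The difference in detected fragments turned to 84 at 20 CPM or more, where fewer reads suffice in the shallower nicotine libraries, to 39.7 after thinning and to 20.3 after thinning over fragments with at least 20 CPM in a library other than nicotine 1, the last chosen after the data were seen, and ran from -23.3 to -4.33 with a library left out. Length kept its direction, from -1.02 to -0.555 nt.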

Other observations

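Tests chosen only after the result was seen were that of nicotine 1 as the source of the tRF-3 difference, that of read number on the median change, those of nicotine 1 over fragments with at least 20 CPM in all 6 libraries, and the splits of the libraries. The other tests had their predictions written before their results were seen. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 fragments, 0 families and 8 lists past the threshold, and the highest of the other splits gave 5, 2 and 9. As many as in the real split were found in 10, 10 and 2 of the 10 splits.

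Tryptophan tRNA fragments, singled out after their values were seen, took 1.11% of the listed reads in nicotine 1 and 0.115% to 0.271% in the other 5 libraries. Histidine tRNA fragments took 1.35% ± 0.697 in saline and 1.02% ± 0.573 in nicotine libraries, and serine tRNA fragments 1.15% ± 0.360 and 1.84% ± 0.513 (SD, n = 3 each), with overlap in both.

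The tRF-3 share of listed reads was 2.32 percentage points higher in nicotine libraries. Over fragments with at least 20 CPM in all 6 libraries the difference was 2.03 points without overlap. This argues against fragments listed through only some libraries as the cause. The same minimum chose that subset, so the minimum as a whole is not tested. Further explanations stay open. With Gly tRNA fragments left out, and so relative to fewer reads, the ratio of nicotine to saline went from 1.72 to 1.34. The difference was 5.06 points of these reads, and 1.38 without nicotine 1, which had 27.3%. The groups overlapped, with nicotine 3 at 14.4% inside the saline range of 13.5% to 16.3%, so a smaller share of Gly reads may account for part of it. Without nicotine 1 the difference was 1.13 points, just under 50% of the full difference and still without overlap, so that library may account for a large part of it. Thinning leaves an expected share as it is, so it does not test read number on the share. For the tRF-3 list the adjusted p went from 0.00128 to a median of 0.00477 with thinned reads. An effect of nicotine stays untested beside these and beside RNA input and library making.

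The median fragment had a log2 fold change of 0.28. Over fragments with at least 20 CPM in all 6 libraries the median was 0.25 (0.17 to 0.35 with a library left out). This argues against fragments listed through only some libraries as the only source. The same minimum chose that subset, and it took 2 or 3 reads in nicotine libraries and 4 to 8 in saline libraries. The listing minimum as a whole is therefore not tested. The share taken by Gly and unlisted reads alone is argued against by a median of 0.20 relative to the listed non-Gly reads (0.11 to 0.31 with a library left out). Other abundant fragments still set that total, so it does not test the scaling as a whole. The median was -0.08 after TMM, -0.03 after median ratio and 0.02 after quantile normalization, so its sign depends on the scaling. With every library thinned to the smallest total the median was 0.333 (0.31 to 0.42 over 20 draws). This argues against the lower number of reads within this list alone. The list itself was chosen on unthinned reads, so thinning does not test depth acting through the listing. An effect of depth through the listing, of the scaling, of treatment, or of RNA input and library making, stays open.

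Nicotine 1 had a mean rank correlation of 0.767 with the other libraries. Counting noise of the shallowest library is argued against, since with all libraries thinned to its total the value was 0.751 against 0.796 to 0.809 for the others. The listing minimum alone was left undecided over fragments with at least 20 CPM in another library, with 0.812 against 0.826 to 0.863, below the others by less than their range. It is argued against over the 258 fragments with at least 20 CPM in all 6 libraries, with 0.845 against 0.876 to 0.886. Both together cannot be told apart from a difference of the library, since over these fragments with thinned reads the value was 0.834 against 0.851 to 0.868, and it lay below all the others in every one of 100 draws but by more than their range in 39%. The bound was first set on the mean of the draws, which passed it with a gap of 0.0172 against a range of 0.0169. It was then set on 95% of the draws, because that margin was under the SD over draws of 0.0083. No biological explanation was tested, as the design gives none for a single rat.

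The ratio of the 32 nt to the 31 nt form of the Gly-CCC 5' fragment varied between libraries, with log2 values of 0.19 to 1.13. A hypothesis was that the 3' ends of 5' fragments shift together in a library, which may be technical. Over 5 non-Gly tRNAs the mean Pearson r across 6 libraries was 0.385, between the bounds set for and against, and no adjusted permutation p was under 0.05, so the hypothesis stays undecided.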
